A study of Homo sapiens with 9 samples.

How the data were processed

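RNA of LN229 glioblastoma cells was measured by sequencing of polyadenylated RNA in 9 libraries, 3 of wild-type cells (WT) and 3 each of the knockout lines B3 and C4, all kept in DMEM with 5% FBS per the labels. Per the submitters' processing notes, STAR 2.7.3a, Subread 1.6.3 and DESeq2 were used by the authors with genome build hg38. No version of that last tool and no role or order of the tools is given there. The deposited table holds log2 values, scaled between libraries by the authors, for 19356 genes, with a column per library. Their shape is that of a regularized-log transform: the median SD between replicates fell from 0.0452 at values of 8 to 12 to 0.00935 at values under 2, so that changes of weakly expressed genes are understated. The transform is not named in the labels, so its nature is inferred from the values. Reads could not be recovered from the table, the read depth is unknown, and no interval that needs counts is given. Among the gene names, 25 are dates in place of their symbols, as spreadsheet software writes them, and these were kept.

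The groups, the comparisons, the tests, 27 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The plan assumed values on a linear scale to which a pseudocount of 1 would be added. Because the values were already log2 values, they were used as deposited, and other pseudocounts were added to the antilog. Genes with a mean antilog of at least 10 over the 9 libraries were tested, which left out 2899 and kept 16457. All libraries entered 1 limma fit (limma 3.58.1, R 4.3.3, statmod 1.5.0 and version 1.17.8 of data.table) with a coefficient per group and empirical Bayes moderation with an intensity trend. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. B3 and C4 were each compared with WT and with each other, and a gene counted as changed in both lines when it was called in each with the same sign. ARNT2 was also compared by an exact permutation test. On data simulated from these values for B3 against WT, 20 draws with 200 changed genes, 34.1% of changes of 0.1 on the log2 scale were recovered, 98.7% of changes of 0.25 and 100% of changes of 0.5, with a mean false share of 7.20%. Far fewer genes changed in these draws than the 7876 called in B3, so the adjusted threshold was stricter in the draws. The recovered and false shares therefore do not carry over to the real comparisons.

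Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists with members present, with an estimated correlation beside it. The self-contained test fry called 23 lists in B3, 22 in C4 and 24 between the lines; it asks whether the genes of a list move on balance in a direction and compares them with no other genes. The rule for named genes took, per comparison, the 8 largest changes up and down among called genes with a mean antilog of at least 50 and groups that do not overlap. It also took the 12 largest shared changes in each direction, up to 4 members per list and a fixed set of markers. Clone-based and uncharacterised names were passed over. Date names, XIST and TSIX were passed over as well, which the rule chosen beforehand did not state. Positions are from GENCODE 29 on GRCh38 (hg38), which held 92.7% of the tested symbols. Shared controls were modelled with 100 simulations of groups without any change. Alternatives were other pseudocounts, filters and scalings, leaving out each library, a replicate block, fits of only the compared groups, robust moderation, fold thresholds and other list tests. The fits intended with edgeR and DESeq2 were not used, because reads could not be recovered. No label gives a sequencing batch or date, and the replicate numbers did not pair the libraries.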

Results

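Polyadenylated RNA was sequenced from LN229, an established human glioblastoma cell line, in 3 groups of 3 libraries: wild-type cells and the CRISPR knockout lines B3 and C4, in which ARNT2 was targeted. The study asked what ARNT2 does in the growth and differentiation of glioblastoma cells. The table gave 19356 genes with a log2 value in each of the 9 libraries, and 16457 genes passed the filter on low values. Read depth is unknown, because the values are scaled log2 values. The 10 most abundant genes took 3.72% to 4.37% of the summed antilogs of a library. Values of weakly expressed genes lie close to the mean of each gene, so their changes are understated. Libraries of the same group differed with an SD of 0.05 to 0.07 across genes, against 0.18 to 0.23 between groups. Principal component 1 held 58.6% of the variance and parted C4 from the rest, and component 2 held 32.5% and parted wild type from B3. The labels do not say that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Changes below are log2 fold changes ± SE from limma with n = 3 libraries per group.

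The targeted gene was lower in both knockout lines. ARNT2, a basic helix-loop-helix PAS transcription factor (ENSG00000172379.20, chromosome 15, 80404350 to 80597937 on the plus strand, GRCh38), had a log2 value of 13.57 ± 0.02 (SD, n = 3) in wild type, 11.89 ± 0.02 (SD, n = 3) in B3 and 12.14 ± 0.09 (SD, n = 3) in C4. The 3 wild-type libraries lay between 13.56 and 13.59 and the 6 knockout libraries between 11.86 and 12.22. ARNT2 RNA was thus at 31.1% of the wild-type level in B3 and at 37.1% in C4. An exact two-sided permutation test gave p = 0.1 for each line, the smallest value that 3 against 3 libraries allow, and limma gave adjusted p = 1.74e-21 for B3 and 1.88e-20 for C4. The level of the RNA does not show whether any protein was made.

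**Figure D1:**
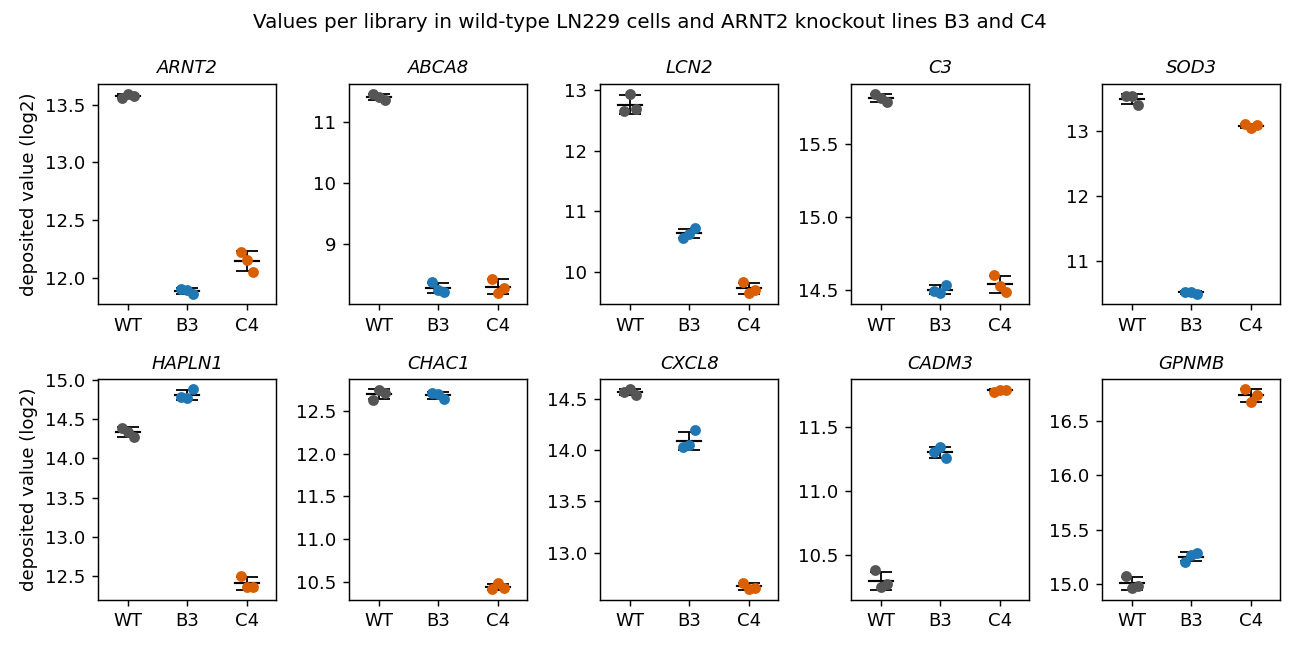
Deposited log2 values of 10 genes (vertical axes, each with its own range that does not start at 0) in the 3 libraries of wild type (WT, grey), B3 (blue) and C4 (orange). Points are libraries, horizontal lines group means and bars the SD (n = 3). ARNT2, ABCA8, LCN2 and C3 lay below wild type in all 6 knockout libraries. CHAC1 was at 10.44 ± 0.03 in C4, 12.68 ± 0.04 in B3 and 12.69 ± 0.06 in wild type.

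In B3 against wild type the large changes were mostly decreases. ABCA8, a lipid transporter of the ATP-binding cassette family, fell by 3.13 ± 0.06, an 8.78-fold lower level. SOD3, the extracellular superoxide dismutase, fell by 2.98 ± 0.03. LCN2, the iron-siderophore binding lipocalin, fell by 2.12 ± 0.06. The cancer-testis antigen genes CTAG2, MAGEA10 and PAGE2 changed by -2.73 ± 0.03, -2.40 ± 0.03 and -2.27 ± 0.05, and the carboxypeptidase-like gene CPXM2 and the microsomal glutathione transferase gene MGST1 by -1.86 ± 0.03 and -1.80 ± 0.04. Among the increases were the cell adhesion gene CADM3 at 1.01 ± 0.04, LYPD1 at 0.93 ± 0.04, the G-protein signalling regulator RGS16 at 0.92 ± 0.04, the dystrophin gene DMD at 0.91 ± 0.04, the Wnt antagonist DKK1 at 0.84 ± 0.05, TMEM171 at 0.83 ± 0.05 and the actin-binding protein gene ENC1 at 0.83 ± 0.02. The pseudogene FRG2DP, at 1.22 ± 0.04, and the PAGE, GAGE, MAGE and CTAG genes belong to families that hold some near-identical copies. The counting could have split the reads of such copies, so the values of those members are uncertain. In all, 7876 genes passed limma's adjusted p of 0.05, 3822 higher and 4054 lower, with a median absolute change of 0.15. By at least 1 on the log2 scale, 2 genes rose and 41 fell. Of the 26 lists tested with camera at a preset correlation of 0.01, 12 were called, and the NF-kB and inflammatory list alone also passed with an estimated correlation. With every library scaled to the same total, 64.2% of the called genes were higher, against 48.5% with the deposited scaling.

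Proliferation genes rose in B3 and astrocyte genes fell. Of the cell cycle and DNA replication genes, 29 of 38 rose and 2 fell (31 changed adjusted over the list alone), with a median of 0.20 (adjusted p = 2.89e-10, and adjusted p = 0.256 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, rose by 0.47 ± 0.03, the mitotic kinase gene AURKA by 0.40 ± 0.03, the cyclin gene CCNA2 by 0.39 ± 0.03 and the proliferation marker MKI67 by 0.18 ± 0.04. The p53 targets and CDK inhibitors, many but not all of whose products restrain the cell cycle or promote cell death, rose as well: 13 of 21 rose and 2 fell (16 changed adjusted over the list alone), with adjusted p = 0.00106, and adjusted p = 0.336 with an estimated correlation. TP53INP1 rose by 0.39 ± 0.04, the apoptosis effector BAX by 0.28 ± 0.03 and the p21 gene CDKN1A by 0.12 ± 0.02. Astrocyte genes fell as a list: 3 of 18 rose and 11 fell (14 changed adjusted over the list alone), with adjusted p = 0.0229, and adjusted p = 0.256 with an estimated correlation. The glial filament gene GFAP and the calcium-binding protein gene S100B nevertheless rose, by 0.25 ± 0.05 and 0.20 ± 0.03. GFAP was weakly expressed, at values of 6.61 to 6.98 over the 9 libraries, against library medians of 10.62 to 10.65. Neural and glioma stem cell genes were not called, with 7 up, 9 down and 16 adjusted over the list alone, of 28, adjusted p = 0.972. Neuron genes had 1 up, 6 down and 7 adjusted over the list alone, of 17, adjusted p = 0.212. Oligodendrocyte lineage genes had 4 up, 7 down and 12 adjusted over the list alone, of 14, adjusted p = 0.196. SOX2, a stem cell transcription factor, rose by 0.25 ± 0.03 and the neuronal tubulin gene TUBB3 by 0.27 ± 0.03, while the stem cell filament gene NES (0.02), the neuronal gene MAP2 (0.04), the glial factor gene OLIG2 (0.07) and the adhesion receptor gene CD44 (0.04) did not pass the test. NES was called without wild-type replicate 1, at adjusted p = 0.0359 in a range of 0.0359 to 0.975 over the alternatives. OLIG2 was called without B3 replicate 3, at adjusted p = 0.0160 in a range of 0.00754 to 0.289. With every library at the same total, MAP2, OLIG2 and CD44 were called (adjusted p = 0.00839, 0.00754 and 0.0180), where MAP2 ranged from 0.00839 to 0.332 and CD44 from 0.0180 to 0.562 over the alternatives.

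Inflammatory, matrix and growth factor response genes fell in B3. Of the NF-kB and inflammatory genes, 1 of 24 rose and 15 fell (18 changed adjusted over the list alone), with adjusted p = 5.34e-06, and adjusted p = 0.0475 with an estimated correlation. The interleukin gene IL1B changed by -0.83 ± 0.05, IL1A by -0.69 ± 0.04 and LIF, a cytokine of the interleukin 6 family, by -0.53 ± 0.02. Among the immediate early genes, which respond to growth factors within minutes, 3 of 19 rose and 12 fell (15 changed adjusted over the list alone), with adjusted p = 0.000786, and adjusted p = 0.351 with an estimated correlation. EGR1 and NR4A1 changed by -0.86 ± 0.03 and -0.55 ± 0.02. Of the receptor tyrosine kinases and MAPK feedback genes, 4 of 26 rose and 15 fell (19 changed adjusted over the list alone), with adjusted p = 0.0229, and adjusted p = 0.351 with an estimated correlation, and the receptor genes FGFR1 and EGFR changed by -0.54 ± 0.03 and -0.53 ± 0.04. Collagen and extracellular matrix genes gave the counts 3 higher and 16 lower of 29 (20 adjusted over the list alone), with adjusted p = 0.000103, and adjusted p = 0.351 with an estimated correlation. COL12A1 and the laminin gene LAMB1 changed by -0.71 ± 0.03 and -0.43 ± 0.03.

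The bHLH-PAS family list, to which ARNT2 itself belongs, was called in B3: 2 of 13 rose and 8 fell (11 changed adjusted over the list alone), with adjusted p = 0.0229, and adjusted p = 0.342 with an estimated correlation. Without ARNT2, a test chosen after the values were seen, 2 of 12 rose and 7 fell (10 adjusted over the list alone), and the call ended at adjusted p = 0.124, in a range of 0.0118 to 0.124 over the alternatives. NPAS1 and ARNTL2 changed by -0.32 ± 0.06 and -0.31 ± 0.04, the dioxin receptor gene AHR by -0.16 ± 0.02, and the paralogue ARNT did not pass the test at 0.06. ARNT was called without B3 replicate 3 (adjusted p = 0.0172), with a filter of 50 (0.0488) and with every library at the same total (0.00326), in a range of 0.00326 to 0.184 over the alternatives. Endothelial and pericyte markers, included as genes of other cell types, gave 0 higher and 7 lower of 11 (7 adjusted over the list alone), with adjusted p = 0.00379, and adjusted p = 0.256 with an estimated correlation, and the pericyte marker RGS5 changed by -1.22 ± 0.05. The ribosomal protein genes fell by small amounts, 21 of 24 (23 adjusted over the list alone), with a median of -0.16 and adjusted p = 2.52e-05, and adjusted p = 0.505 with an estimated correlation. Histone genes of the replication-dependent clusters rose, 9 of 10 (9 adjusted over the list alone), with a median of 0.54 and adjusted p = 5.67e-07, and adjusted p = 0.114 with an estimated correlation. Some members of these clusters are alike in sequence, and most normally lack a poly(A) tail. HIST1H1C rose by 0.75 ± 0.05 and HIST1H2BK by 0.66 ± 0.03.

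Further lists were not called in B3. Hypoxia inducible factor targets had 8 up, 13 down and 21 adjusted over the list alone, of 32, adjusted p = 0.135, with NDRG1, a stress-response gene, at -0.92 ± 0.03 and VEGFA, the vascular growth factor gene, at -0.26 ± 0.03. Aryl hydrocarbon receptor targets had 3 up, 4 down and 8 adjusted over the list alone, of 9, adjusted p = 0.596. The epithelial to mesenchymal transition and invasion genes had 14 up, 10 down and 26 adjusted over the list alone, of 30, adjusted p = 0.457. Interferon response genes had 12 up, 11 down and 23 adjusted over the list alone, of 32, adjusted p = 0.543. Notch pathway genes had 2 up, 9 down and 11 adjusted over the list alone, of 19, adjusted p = 0.124. Wnt pathway genes had 5 up, 12 down and 17 adjusted over the list alone, of 21, adjusted p = 0.143. TGF-beta and BMP pathway genes had 7 up, 11 down and 18 adjusted over the list alone, of 23, adjusted p = 0.245. Cholesterol biosynthesis genes had 12 up, 6 down and 18 adjusted over the list alone, of 22, adjusted p = 0.124. The unfolded protein and amino acid stress genes had 8 up, 10 down and 19 adjusted over the list alone, of 23, adjusted p = 0.596. Immune cell markers had 1 up, 0 down and 1 adjusted over the list alone, of 8, adjusted p = 0.972. Epithelial cell markers had 0 up, 3 down and 3 adjusted over the list alone, of 13, adjusted p = 0.124, and the keratin genes KRT8 and KRT18 changed by -0.64 ± 0.04 and -0.33 ± 0.03. The epithelial list was called without wild-type replicate 1, at adjusted p = 0.0272, in a range of 0.0272 to 0.482 over the alternatives. For the stem cell and immune lists the median, mean and test differed in sign.

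In C4 against wild type, the largest decreases among the named genes were those of ABCA8 and LCN2. ABCA8 changed by -3.11 ± 0.06 and LCN2 by -3.02 ± 0.06, an 8.13-fold lower level. TMPRSS15, which encodes the protease enteropeptidase, changed by -2.86 ± 0.03, the bradykinin receptor gene BDKRB2 by -2.30 ± 0.04, and CHAC1, a glutathione-degrading enzyme induced by amino acid stress, by -2.25 ± 0.03. The adhesion protein gene FLRT2, the hyaluronan link protein gene HAPLN1 and the chemokine gene CXCL8 changed by -1.93 ± 0.05, -1.93 ± 0.04 and -1.89 ± 0.03. VEGFA fell by 1.63 ± 0.03. Upward, the adhesion genes CADM2, CADM3 and CHL1 reached 1.74 ± 0.04, 1.49 ± 0.04 and 1.70 ± 0.03, the membrane glycoprotein gene GPNMB 1.73 ± 0.03, the melanin synthesis gene DCT 1.46 ± 0.05, the cancer-testis gene MAGEC2 1.70 ± 0.05, MUM1L1 1.42 ± 0.04 and ILDR2 1.36 ± 0.05. In all, 9244 genes passed limma's adjusted p of 0.05, 4644 higher and 4600 lower, with a median absolute change of 0.17. Of these, 19 rose and 63 fell by at least 1 on the log2 scale. Camera called 13 of the 26 lists, and the NF-kB list and the unfolded protein and amino acid stress list also passed with an estimated correlation. Scaling every library to the same total put 61.5% of the called genes on the higher side, against 50.2% with the deposited scaling.

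Unfolded protein and amino acid stress genes, tested as 1 list, and inflammatory genes fell in C4. Of the unfolded protein and amino acid stress genes, 4 of 23 rose and 16 fell (22 changed adjusted over the list alone), with a median of -0.67 (adjusted p = 3.36e-09, and adjusted p = 0.00996 with an estimated correlation). HSPA5 and HSP90B1, chaperone genes of the endoplasmic reticulum picked after their values were seen, were at 0.07 and 0.03. They do not stand for the other unfolded protein genes of the list, which were not tested apart from the amino acid stress genes. The asparagine synthetase gene ASNS changed by -1.64 ± 0.03, the pseudokinase gene TRIB3 by -1.51 ± 0.03, and the transcription factor genes DDIT3 and ATF4 by -1.39 ± 0.04 and -1.01 ± 0.03. Of the NF-kB and inflammatory genes, 2 of 24 rose and 21 fell (23 changed adjusted over the list alone), with a median of -0.57 (adjusted p = 1.19e-13, and adjusted p = 0.00420 with an estimated correlation), and IL1A and LIF changed by -1.66 ± 0.04 and -1.05 ± 0.02. Immediate early genes fell, with 3 higher and 14 lower of 19 (18 adjusted over the list alone) and adjusted p = 1.58e-05, and adjusted p = 0.221 with an estimated correlation, EGR2 at -1.22 ± 0.03 and EGR1 at -1.02 ± 0.03. Receptor tyrosine kinase and MAPK feedback genes gave 5 higher and 17 lower of 26 (23 adjusted over the list alone), with adjusted p = 0.00108, and adjusted p = 0.145 with an estimated correlation. The receptor genes MET and PDGFRA changed by -0.77 ± 0.02 and -0.63 ± 0.03.

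Interferon response genes rose in C4. Of this list, 28 of 32 rose and 2 fell (30 changed adjusted over the list alone), with a median of 0.35 (adjusted p = 1.86e-12, and adjusted p = 0.145 with an estimated correlation). The ubiquitin-like modifier gene ISG15 rose by 0.87 ± 0.05, IFIT1 by 0.69 ± 0.04, the transcription factor gene IRF9 by 0.63 ± 0.03 and OAS3 by 0.55 ± 0.03. The cholesterol biosynthesis genes rose, with 16 higher and 2 lower of 22 (18 adjusted over the list alone) and adjusted p = 0.0001002, and adjusted p = 0.145 with an estimated correlation, HMGCS1 at 0.55 ± 0.02 and INSIG1, a feedback inhibitor of the pathway, at 0.51 ± 0.03. Astrocyte genes rose, with 12 higher and 2 lower of 18 (14 adjusted over the list alone) and adjusted p = 0.00891, and adjusted p = 0.145 with an estimated correlation. AGT, the angiotensinogen gene expressed by astrocytes, rose by 0.94 ± 0.05, and S100B and the weakly expressed GFAP by 0.27 ± 0.03 and 0.23 ± 0.05. Histone genes rose (7 of 10, 7 adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.145 with an estimated correlation), and 24 of 24 ribosomal protein genes fell (24 adjusted over the list alone, median -0.28, adjusted p = 4.81e-10, and adjusted p = 0.360 with an estimated correlation).

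Epithelial to mesenchymal transition and invasion genes fell in C4, with 7 higher and 16 lower of 30 (23 adjusted over the list alone) and adjusted p = 0.0217, and adjusted p = 0.145 with an estimated correlation. The integrin genes ITGB3 and ITGA5 changed by -0.81 ± 0.03 and -0.79 ± 0.02. That call ended without the genes in regionally shifted windows described further on, at adjusted p = 0.0769, in a range of 0.0119 to 0.0769 over the alternatives. Calls of the developmental signalling lists lay near the threshold. Notch pathway genes gave 3 higher and 10 lower of 19 (13 adjusted over the list alone), with adjusted p = 0.0477, and adjusted p = 0.145 with an estimated correlation, and the ligand gene JAG1 and receptor gene NOTCH3 changed by -0.83 ± 0.03 and -0.62 ± 0.04. The Notch call ended without wild-type replicate 1 (adjusted p = 0.0765), B3 replicate 2 (0.0508), B3 replicate 3 (0.0506), C4 replicate 1 (0.0536) or C4 replicate 2 (0.0602), and with the replicate block (0.05003) or a fit of the compared groups alone (0.0510), in a range of 0.00985 to 0.0765 over the alternatives. The TGF-beta and BMP pathway genes gave 6 higher and 13 lower of 23 (19 adjusted over the list alone), with adjusted p = 0.0477, and adjusted p = 0.338 with an estimated correlation, and ID4, an inhibitor of helix-loop-helix factors, went up by 0.74 ± 0.02. Their call ended without wild-type replicate 1 (adjusted p = 0.103), B3 replicate 2 (0.0513), B3 replicate 3 (0.0506) or C4 replicate 1 (0.0573), with a filter of 50 (0.0582), with the replicate block (0.05003), with a fit of the compared groups alone (0.0510) and without genes in shifted windows (0.172), in a range of 0.0257 to 0.172 over the alternatives. The Wnt pathway genes gave 5 higher and 13 lower of 21 (18 adjusted over the list alone), with adjusted p = 0.0404, and adjusted p = 0.470 with an estimated correlation, and the feedback genes NKD2 and NKD1 and the receptor gene LGR5 changed by -0.94 ± 0.04, -0.87 ± 0.05 and -0.83 ± 0.05. Without wild-type replicate 1 the Wnt list had adjusted p = 0.0934, and without genes in shifted windows 0.0997, in a range of 0.0181 to 0.0997 over the alternatives.

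The remaining lists were not called in C4, and the mitochondrially encoded list had 0 members in the table. Neural and glioma stem cell genes had 8 up, 8 down and 16 adjusted over the list alone, of 28, adjusted p = 0.952. SOX2 (0.03) and NES (0.01) did not pass the test, although SOX2 was called without C4 replicate 1, at adjusted p = 0.0467 in a range of 0.0467 to 0.751. The transcription factor gene KLF4 changed by -0.62 ± 0.03. Neuron genes had 5 up, 7 down and 12 adjusted over the list alone, of 17, adjusted p = 0.653, with MAP2 up by 0.31 ± 0.02 and the synaptic gene SYT1 at -0.50 ± 0.03. Oligodendrocyte lineage genes had 6 up, 6 down and 12 adjusted over the list alone, of 14, adjusted p = 0.952, with OLIG1 and OLIG2 up by 0.66 ± 0.05 and 0.32 ± 0.03 and the proteoglycan gene CSPG4 and the myelin gene MAG at -0.65 ± 0.03 and -0.71 ± 0.02. Cell cycle and DNA replication genes had 9 up, 15 down and 24 adjusted over the list alone, of 38, adjusted p = 0.424, with MKI67 up by 0.27 ± 0.04 and CDKN1A by 0.13 ± 0.02. TUBB3 and CD44 rose by 0.16 ± 0.03 and 0.10 ± 0.03. The p53 targets and CDK inhibitors had 9 up, 8 down and 17 adjusted over the list alone, of 21, adjusted p = 0.952. Hypoxia inducible factor targets had 9 up, 10 down and 20 adjusted over the list alone, of 32, adjusted p = 0.538, with HIF1A at -0.31 ± 0.02 and the lactate dehydrogenase gene LDHA up by 0.31 ± 0.03. Aryl hydrocarbon receptor targets had 2 up, 4 down and 7 adjusted over the list alone, of 9, adjusted p = 0.328. The bHLH-PAS family genes had 4 up, 7 down and 11 adjusted over the list alone, of 13, adjusted p = 0.328. Circadian clock genes had 5 up, 3 down and 8 adjusted over the list alone, of 15, adjusted p = 0.952. Collagen and extracellular matrix genes had 7 up, 10 down and 17 adjusted over the list alone, of 29, adjusted p = 0.424, and the proteoglycan gene BGN changed by -0.86 ± 0.03. Immune cell markers had 0 up, 1 down and 1 adjusted over the list alone, of 8, adjusted p = 0.952. Epithelial cell markers had 0 up, 3 down and 3 adjusted over the list alone, of 13, adjusted p = 0.337. Endothelial and pericyte markers had 1 up, 3 down and 4 adjusted over the list alone, of 11, adjusted p = 0.487. For the stem cell, oligodendrocyte, p53, hypoxia, clock and immune lists the median, mean and test differed in sign.

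**Figure D2:**
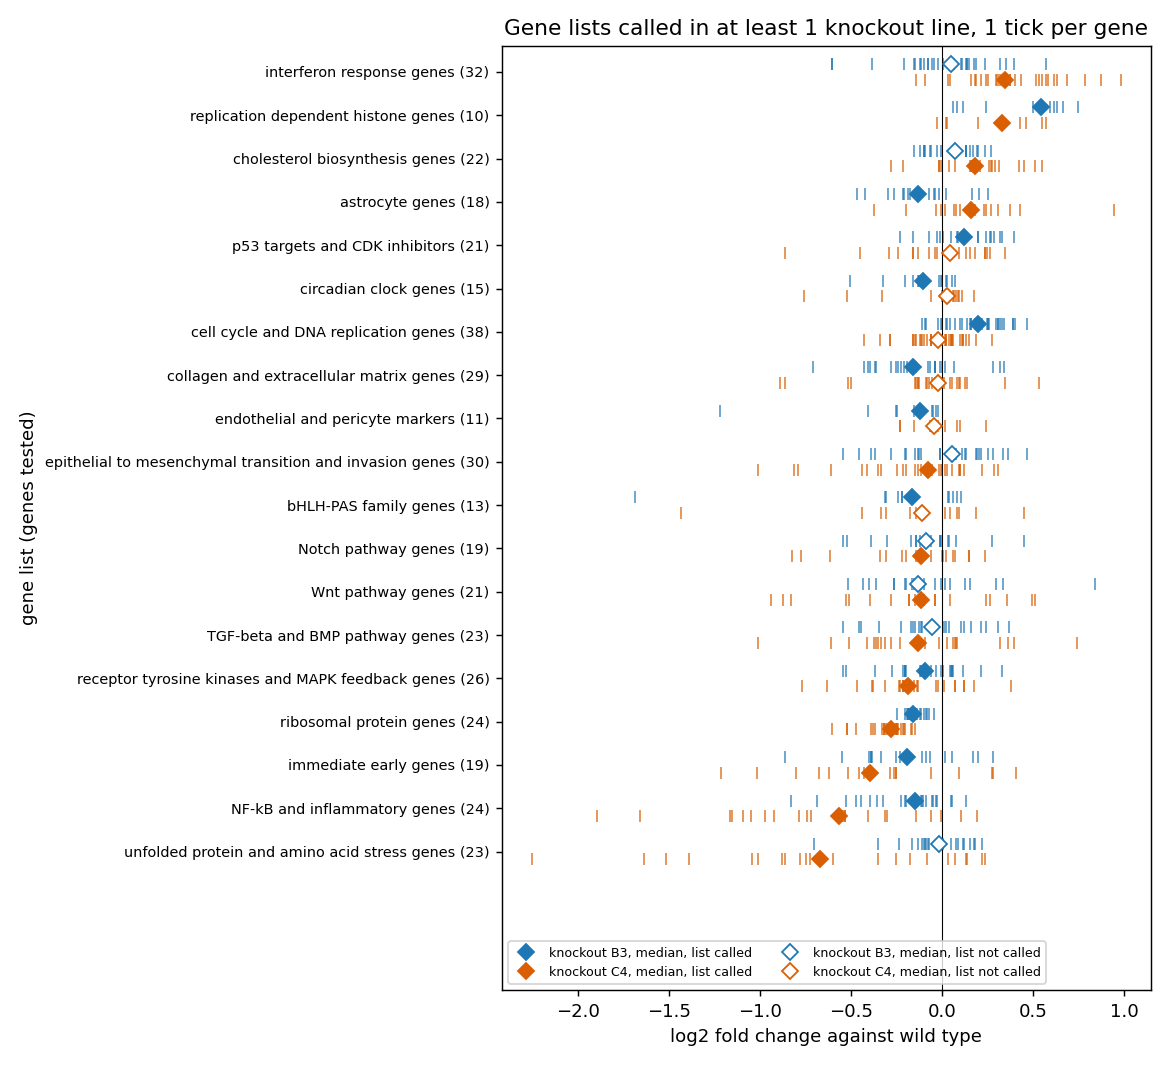
Gene lists called in B3 or C4 (vertical axis, with the number of genes tested) against the log2 fold change from wild type (horizontal axis) in B3 (blue) and C4 (orange). Ticks are genes, diamonds are list medians, and a filled diamond marks a list past adjusted p of 0.05 with a preset correlation of 0.01. The NF-kB and inflammatory list had medians of -0.15 in B3 and -0.57 in C4, and the astrocyte list -0.14 and 0.16. The call of the bHLH-PAS list in B3 ended without ARNT2.

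Circadian clock genes fell in B3 at the edge of the threshold, with 0 higher and 8 lower of 15 (8 adjusted over the list alone) and adjusted p = 0.0456, and adjusted p = 0.351 with an estimated correlation. BHLHE41, a repressor of the clock, and the period gene PER1 changed by -0.51 ± 0.04 and -0.33 ± 0.03. That call ended without wild-type replicate 2 (adjusted p = 0.0734), wild-type replicate 3 (0.0837), B3 replicate 1 (0.0531), B3 replicate 2 (0.0514) or the genes in shifted windows (0.120), in a range of 0.0261 to 0.120 over the alternatives.

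Genes that changed the same way in both knockout lines numbered 3966, of which 1908 were higher and 2058 lower. With every library at the same total there were 2937 higher and 1444 lower, so the larger side depends on the scaling. It also turned without the genes in regionally shifted windows described further on, with 1863 higher and 1771 lower. ABCA8 and LCN2 had the largest shared decreases among the named genes. The 12 with the largest shared decrease also held ABCA6, a neighbour of ABCA8 on chromosome 17 (-1.42 in B3 and -1.40 in C4), the complement gene C3 (-1.31 in B3 and -1.27 in C4), the ubiquitin-like gene UBD (-1.43 in B3 and -1.78 in C4) and the growth factor binding protein gene IGFBP3 (-1.39 in B3 and -1.73 in C4). Further genes of the 12 were PAGE2 and GAGE1, the phospholipase-like gene PLBD1 (-1.66 in B3 and -1.77 in C4), the heparan sulfate sulfotransferase gene HS6ST2 (-1.45 in B3 and -1.69 in C4), the S6 kinase gene RPS6KA2 (-1.28 in B3 and -1.47 in C4) and ARNT2 itself. The shared increases were smaller. CADM3 and RGS16 (0.92 in B3 and 0.90 in C4) led them, with the PI3-kinase subunit gene PIK3R3 (0.65 in B3 and 0.70 in C4), TMEM171 (0.83 in B3 and 0.65 in C4), the semaphorin receptor gene NRP2 (0.67 in B3 and 0.57 in C4), DKK1 (0.84 in B3 and 0.49 in C4), CIITA, the master activator of MHC class II genes (0.53 in B3 and 1.08 in C4), ISG15 (0.57 in B3 and 0.87 in C4), FXYD7 (0.48 in B3 and 0.57 in C4), GPR158 (0.48 in B3 and 1.16 in C4) and the histone genes HIST1H2BK and HIST1H2BD.

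**Figure D3:**
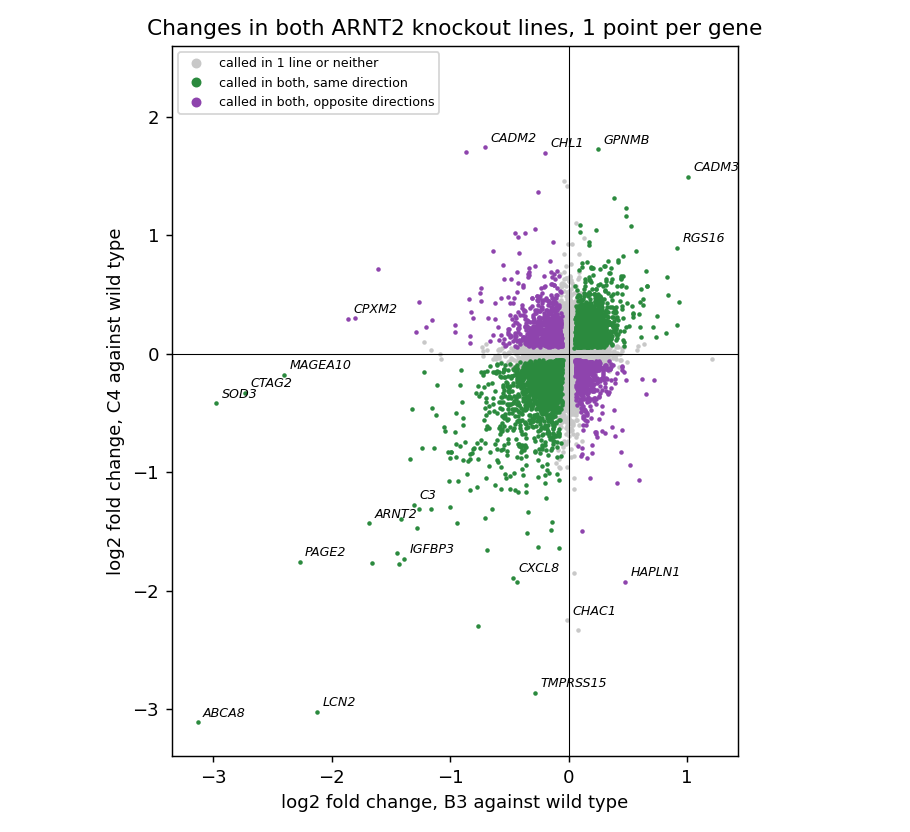
Log2 fold change against wild type in B3 (horizontal axis) and C4 (vertical axis), 1 point for each of the 16457 genes tested. Green points passed adjusted p of 0.05 in both lines in the same direction (3966 genes) and purple points in opposite directions (1412 genes). ABCA8 lies at -3.13 and -3.11, and HAPLN1 at 0.48 and -1.93.

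Camera called 5 lists in the same direction in both lines, and the NF-kB list alone passed in both with an estimated correlation. Of the 24 NF-kB and inflammatory genes 15 were lower in both lines, 1 was higher in both and 0 went opposite ways. All but 3 of the 24 ribosomal protein genes were lower in both. Receptor tyrosine kinase and MAPK feedback genes had 12 of 26 lower in both, 2 higher in both and 2 opposite, and immediate early genes 11 of 19 lower in both, 2 higher and 1 opposite. Of the 10 histone genes 7 were higher in both. The other lists had adjusted p = 0.505 and 0.360 with an estimated correlation for ribosomal protein genes in B3 and C4, 0.351 and 0.145 for receptor tyrosine kinases, 0.351 and 0.221 for immediate early genes and 0.114 and 0.145 for histone genes. The astrocyte list was called in opposite directions (adjusted p = 0.256 and 0.145 with an estimated correlation), with 10 of 18 genes opposite, 2 higher in both and 1 lower in both. S100B and the weakly expressed GFAP rose in both lines, and NDRG1, EGR1 and TGFBI fell in both.

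Both lines were compared with the same wild-type libraries, which makes fold changes alike without any effect. In 100 simulations of unchanged groups at most 2 genes were called the same way in both, against 3966 observed. Neither simulated line held any change, so this does not show how many genes lines with separate changes would share. Independent lists of these sizes would share 1079 higher genes and 1133 lower genes, and the observed numbers were 1.77 and 1.82 times as many. Across genes, which are not independent replicates, the fold changes of the lines had a correlation of 0.375, below the mean of 0.498 simulated with shared controls and no effect. The same sign was found in 63.0% of genes, against 66.6% simulated. Both simulated values come from the spread between libraries alone and are no benchmark for lines with changes of their own. The covariance was 0.0143 against a simulated mean of 0.000605, a difference of 0.0137. With 3 wild-type libraries the controls could not be split, and part of the excess over independent lists may come from them. Another 1412 genes were called in opposite directions in the lines, 26.3% of the genes called in both. A contrast of the mean of both lines against wild type called 8529 genes, a set that also takes genes that changed in 1 line.

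The lines also differed from each other. In C4 against B3, MAGEC2 was 2.57 ± 0.05 higher, SOD3 2.56 ± 0.03, CADM2 2.45 ± 0.04, CTAG2 2.40 ± 0.03, the neurite growth gene NRN1 2.32 ± 0.04, MAGEA10 2.23 ± 0.03, CPXM2 2.16 ± 0.03 and MGST1 2.11 ± 0.04. Lower in C4 than in B3 were TMPRSS15 (-2.58 ± 0.03), HAPLN1 (-2.40 ± 0.04), CHAC1 (-2.24 ± 0.03), the secreted glycoprotein gene STC2 (-1.90 ± 0.03), the cartilage proteoglycan gene ACAN (-1.66 ± 0.03), the peptide hormone gene ADM2 (-1.61 ± 0.04), ASNS (-1.56 ± 0.03) and BDKRB2 (-1.53 ± 0.04). ARNT2 was 0.25 ± 0.03 higher in C4. In this direct test 9284 genes differed, 4705 higher and 4579 lower in C4, with 50 and 27 of them by at least 1 on the log2 scale. Camera called 11 of 26 lists, and the epithelial to mesenchymal transition, NF-kB and amino acid stress lists also passed with an estimated correlation.

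Interferon response genes were higher in C4 than in B3, with a median of 0.31 and 31 higher and 0 lower of 32 (31 adjusted over the list alone). Their test gave adjusted p = 6.39e-12, and adjusted p = 0.108 with an estimated correlation. Astrocyte genes were higher, with a median of 0.23 and 11 higher and 1 lower of 18 (13 adjusted over the list alone), and with adjusted p = 0.000315, and adjusted p = 0.0625 with an estimated correlation. Cholesterol biosynthesis genes were higher, with a median of 0.12 and 15 higher and 3 lower of 22 (19 adjusted over the list alone), and with adjusted p = 0.00320, and adjusted p = 0.288 with an estimated correlation. Lower in C4 were the unfolded protein and amino acid stress genes, with a median of -0.54 and 3 higher and 17 lower of 23 (20 adjusted over the list alone). This list had adjusted p = 1.33e-09, and adjusted p = 0.00850 with an estimated correlation. The NF-kB and inflammatory genes were lower, with a median of -0.44 and 0 higher and 19 lower of 24 (20 adjusted over the list alone), and with adjusted p = 9.19e-11, and adjusted p = 0.00850 with an estimated correlation. Cell cycle and DNA replication genes were lower, with a median of -0.22 and 4 higher and 28 lower of 38 (32 adjusted over the list alone), and with adjusted p = 4.00e-09, and adjusted p = 0.247 with an estimated correlation. The p53 targets and CDK inhibitors were lower, with a median of -0.05 and 1 higher and 9 lower of 21 (10 adjusted over the list alone), and with adjusted p = 0.0124, and adjusted p = 0.439 with an estimated correlation. Epithelial to mesenchymal transition and invasion genes had 2 higher and 18 lower of 30 (20 adjusted over the list alone), with adjusted p = 0.000256, and adjusted p = 0.0317 with an estimated correlation. Ribosomal protein genes had 0 higher and 16 lower of 24 (16 adjusted over the list alone), with adjusted p = 0.000315, and adjusted p = 0.698 with an estimated correlation. Immediate early genes had 5 higher and 11 lower of 19 (16 adjusted over the list alone), with adjusted p = 0.0228, and adjusted p = 0.582 with an estimated correlation. They lost their call without the genes in shifted windows, at adjusted p = 0.167, in a range of 0.00608 to 0.167 over the alternatives. Histone genes had 0 higher and 7 lower of 10 (7 adjusted over the list alone), with adjusted p = 0.0437, and adjusted p = 0.439 with an estimated correlation. They lost it with a filter of 50 (adjusted p = 0.0971) and without B3 replicate 1 (0.0601), B3 replicate 3 (0.0900), C4 replicate 1 (0.0558) or C4 replicate 3 (0.0517), in a range of 0.0190 to 0.0971.

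Other lists did not pass the direct test between the lines. Collagen and extracellular matrix genes came close, with 16 up, 6 down and 22 adjusted over the list alone, of 29, adjusted p = 0.0507 and BGN and COL12A1 at -0.50 ± 0.03 and 0.56 ± 0.03. That list was called without wild-type replicate 1 (adjusted p = 0.0273), wild-type replicate 2 (0.0483), B3 replicate 2 (0.0318), C4 replicate 1 (0.0224) or C4 replicate 2 (0.0429), and with no filter (0.0238), TMM scaling (0.0471), equal library totals (0.0441) or a fit of the compared groups alone (0.0346), in a range of 0.0224 to 0.136 over the alternatives. Stem cell genes had 9 up, 7 down and 16 adjusted over the list alone, of 28, adjusted p = 0.874. Neuron genes had 5 up, 5 down and 10 adjusted over the list alone, of 17, adjusted p = 0.985. Oligodendrocyte lineage genes had 8 up, 6 down and 14 adjusted over the list alone, of 14, adjusted p = 0.596. Hypoxia inducible factor targets had 13 up, 11 down and 25 adjusted over the list alone, of 32, adjusted p = 0.874. Aryl hydrocarbon receptor targets had 5 up, 3 down and 8 adjusted over the list alone, of 9, adjusted p = 0.748. The bHLH-PAS family genes had 5 up, 3 down and 8 adjusted over the list alone, of 13, adjusted p = 0.469. Circadian clock genes had 6 up, 3 down and 9 adjusted over the list alone, of 15, adjusted p = 0.408. Notch pathway genes had 4 up, 7 down and 11 adjusted over the list alone, of 19, adjusted p = 0.335. Wnt pathway genes had 7 up, 10 down and 18 adjusted over the list alone, of 21, adjusted p = 0.346. TGF-beta and BMP pathway genes had 7 up, 11 down and 19 adjusted over the list alone, of 23, adjusted p = 0.364. Receptor tyrosine kinase and MAPK feedback genes had 7 up, 14 down and 21 adjusted over the list alone, of 26, adjusted p = 0.124. Immune, epithelial and endothelial or pericyte markers had adjusted p = 0.874, 0.801 and 0.192, with 5 of 8, 3 of 13 and 7 of 11 called adjusted over the list alone. For the neuron, hypoxia, aryl hydrocarbon receptor, Wnt, immune and epithelial lists the median, mean and test differed in sign.

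Neighbouring genes shifted together on parts of some chromosomes, a comparison made after the values had been seen. In 326 windows of 40 consecutive genes, 21 windows of B3 and 12 of C4 had a median change beyond the largest of 1000 shuffles of the genes, and no window was shifted in both lines. B3 was lower on chromosome 6 from 57.2 to 99.4 Mb (median -0.36), on chromosome 12 from 0.280 to 55.7 Mb (-0.20) and from 57.0 to 72.3 Mb (-0.17), on chromosome 8 from 0.213 to 38.5 Mb (-0.18), and on segments of chromosomes 5 and 7. C4 was lower on chromosome 2 from 97.1 to 132.6 Mb (-0.38) and from 189.7 to 200.9 Mb (-0.17), on chromosome 8 from 99.0 to 145.1 Mb (-0.29) and from 70.7 to 86.5 Mb (-0.21), and on chromosome 3 from 0.197 to 18.4 Mb (-0.22), and higher on chromosome 6 from 31.8 to 33.1 Mb (0.16), which holds MHC genes. These windows held 8.47% of the genes called in B3 and 4.59% of those called in C4. Without their genes, the Notch list was called in B3 (adjusted p = 0.0118 in a range of 0.0118 to 0.167 over the alternatives), as was the cholesterol list (0.0360 in a range of 0.0360 to 0.221). Between the lines the receptor tyrosine kinase list was then called (0.0175 in a range of 0.0175 to 0.200). Among the named genes, MGST1, PLBD1, ARNTL2, BHLHE41, NR4A1, ITGA5, KRT8, KRT18, DDIT3 and LGR5 on chromosome 12, COL12A1 and POU3F2 on chromosome 6, FGFR1 on chromosome 8 and EGR1 and TGFBI on chromosome 5 lay in shifted windows of B3. IL1A and IL1B on chromosome 2, CHL1 and RPL32 on chromosome 3 and NDRG1, ARC and RPL7 on chromosome 8 lay in shifted windows of C4.

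**Figure D4:**
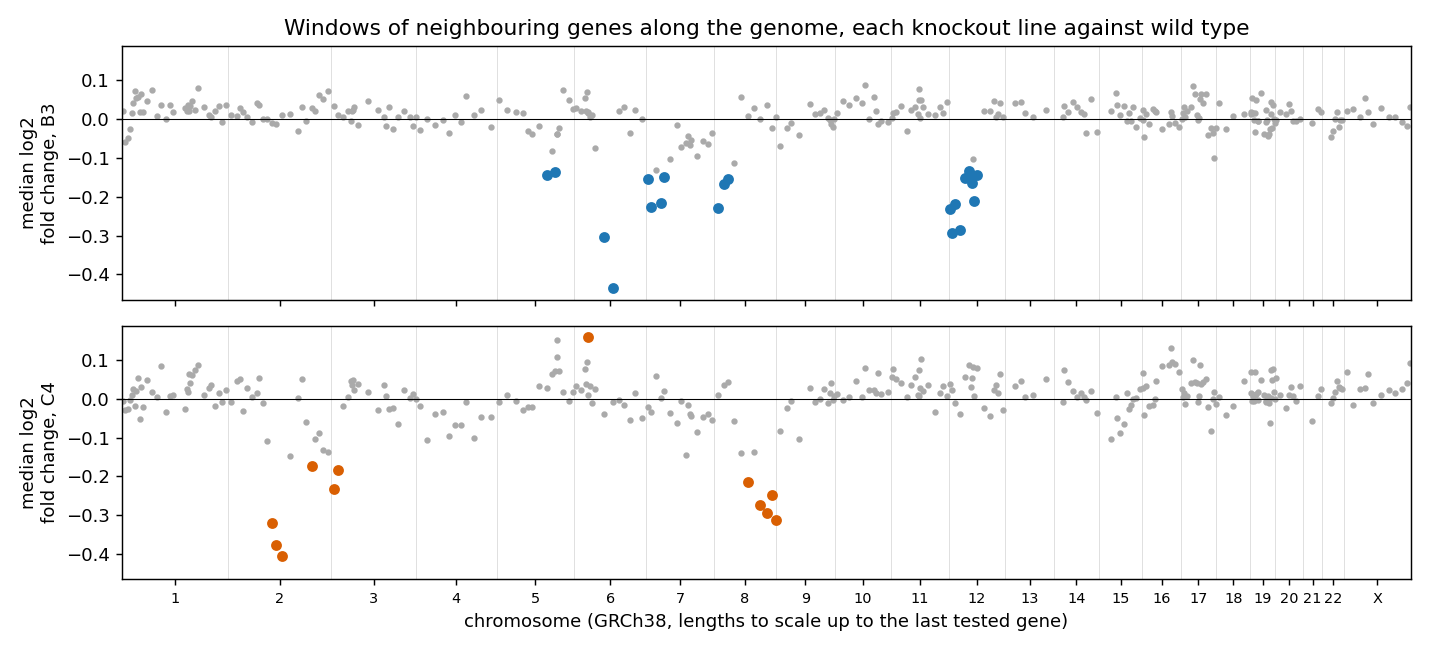
Median log2 fold change against wild type (vertical axes) of 326 windows of 40 neighbouring genes in B3 (top) and C4 (bottom), placed at the middle of each window along the chromosomes (horizontal axis, GRCh38). Coloured points are windows beyond the largest of 1000 shuffles. Blue points gather on chromosomes 5, 6, 7, 8 and 12 and orange points on chromosomes 2, 3, 6 and 8, and all coloured points but the orange point on chromosome 6 are below 0.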

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

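Among the tests in this part, the comparison of aminoacyl-tRNA synthetases was chosen only after the result was seen. The knockout lines differed from each other in 9284 genes by the direct limma test. Of the 10 splits of these 6 libraries 1, the real one, gave as many, and the highest other gave 0. These splits are too few for a share under 0.05.

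Lists differed between the lines by the direct test, in median log2 difference of C4 minus B3: astrocyte genes 0.23, interferon response genes 0.31 and cholesterol biosynthesis genes 0.12. The others were lower in C4. Their medians were -0.22 for cell cycle and DNA replication genes, -0.05 for p53 targets and CDK inhibitors, -0.13 for epithelial to mesenchymal transition and invasion genes and -0.44 for NF-kB and inflammatory genes. They were -0.54 for unfolded protein and amino acid stress genes, -0.16 for immediate early genes, -0.15 for ribosomal protein genes and -0.09 for histone genes. The epithelial to mesenchymal transition, NF-kB and stress lists also passed with an estimated correlation, at adjusted p = 0.0317, 0.00850 and 0.00850. The rest did not pass, with adjusted p = 0.0625 with an estimated correlation for astrocyte genes, 0.108 for interferon, 0.288 for cholesterol, 0.247 for cell cycle, 0.439 for p53, 0.582 for immediate early, 0.698 for ribosomal protein and 0.439 for histone genes.

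Several named genes were called in opposite directions in the lines, and the difference was tested directly. C4 minus B3 was 2.57 for MAGEC2, 2.45 for CADM2, 2.32 for NRN1, 2.16 for CPXM2, 2.11 for MGST1, 1.90 for CHL1 and 1.63 for ILDR2. For AGT it was 1.08 and for the period gene PER3 0.29. It was -2.40 for HAPLN1, -1.66 for ACAN, -1.61 for ADM2, -0.91 for the amino acid transporter gene SLC7A5, -0.73 for LRAT, -0.39 for HIF1A and -0.31 for the filament gene VIM. MGST1 lay in a shifted window of B3 and CHL1 in a shifted window of C4, where CHL1 went against its neighbours. For some of these genes the call in 1 line ended when a library was left out. ADM2 in B3 lost its call without wild-type replicate 1 (adjusted p = 0.166), wild-type replicate 3 (0.0687), B3 replicate 1 (0.0755) or B3 replicate 3 (0.130), and with the replicate block (0.0501), in a range of 0.00653 to 0.166 over the alternatives. AGT in B3 lost it without wild-type replicate 1 (0.144) or B3 replicate 2 (0.135), and with every library at the same total (0.0897), in a range of 0.0189 to 0.144. HIF1A in B3 lost it without wild-type replicate 3 (0.0821), in a range of 0.000425 to 0.0821. PER3 in C4 lost it without C4 replicate 2 (0.0529), in a range of 0.00100 to 0.0529. VIM in C4 lost it without C4 replicate 2 (0.0503) or C4 replicate 3 (0.0735), in a range of 0.00125 to 0.0735.

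The unfolded protein and amino acid stress genes were lower in C4, with a median of -0.67. After subtracting the median of each gene's window in C4, 109.65% of the list's median was left. The lowest window median in C4 was -0.404, so the subtraction could not have taken all of it away. The values argue only against shifts of whole windows as the full cause. The highest median of the list under the other scalings was -0.64. Those scalings moved all genes of C4 alike, by -0.0019 and 0.029 on the log2 scale, so they could hardly change it. Neither scaling accounts for the lower list. Lower transcription of the targets of ATF4, a regulator of amino acid stress genes, is a candidate explanation, and the cytosolic aminoacyl-tRNA synthetases, many of them ATF4 targets, lay at a median -0.3 from the mitochondrial ones in C4. Whether this follows from ARNT2, from the line or from the culture of C4 stays open, as B3 had a median of -0.02, yet 9 of the 23 genes were lower in both lines, 3 higher in both and 4 opposite, and in B3 DDIT3, in a shifted window, was at -0.70, TRIB3 at -0.35 and ATF4 at -0.17.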

How the results depend on the processing

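Added after the data were seen were the threshold of 0.5 on the log2 scale, the fits without genes in shifted windows and the list tests without ARNT2. The total of called genes per comparison, the correlation of the lines, ARNT2 and the number of called lists stayed within 1.5 times the reported value under every pseudocount, filter, scaling, left-out library, replicate block, 2-group fit and robust fit run, and ARNT2 stayed lower in both lines. The correlation was not computed for the 2-group fits. With an absolute log2 fold change of at least 1 as well, 43 genes changed in B3, 82 in C4, 16 in both and 77 between the lines, and with at least 0.5 there were 283, 556, 105 and 585. A contrast of the mean of both lines called 8529. With an estimated correlation 1 list was called in B3, 2 in C4 and 3 between the lines. The lower gene counts follow from the fold thresholds. With an estimated correlation camera also takes fewer degrees of freedom, so the correlation alone does not account for the lists lost. The contrast of means also takes genes changed in 1 line. Leaving out a library gave 6944 to 8016 genes in B3, 8387 to 9272 in C4, 3431 to 3980 in both and 8363 to 9596 between the lines, with 11 to 13, 10 to 13 and 10 to 12 lists and a correlation of 0.368 to 0.391. ARNT2 ranged from -1.70 to -1.67 in B3 and from -1.47 to -1.39 in C4. With the replicate block the counts were 7504, 8961, 3736 and 9017, but same-number libraries were not alike (r from -0.229 to 0.016), so the numbers do not pair them. Without genes in shifted windows they were 6937, 8307, 3634 and 8102. The larger side then turned in B3 (3651 higher and 3286 lower), in both lines (1863 and 1771) and between the lines (3988 and 4114). With every library at the same total there were 8534 genes in B3 (5480 higher), 9571 in C4 (5887 higher) and 4381 in both (2937 higher and 1444 lower, against 1908 and 2058). Apart from the estimated correlation, 8 results of a list in a comparison lost and 5 gained a call under some alternative, and of results for named genes 16 lost and 22 gained one. No value past the threshold changed sign; the cause was not tested. The calls of the Notch and TGF-beta lists in C4, of ADM2 in B3 and of TGFBI between the lines also ended with the replicate block. The planned edgeR and DESeq2 fits were not run, since reads were not recoverable, and the unknown depth leaves counting error unmeasured.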

Other observations

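Of the tests in this part, the shuffle of neighbouring genes, the covariance after subtracting window medians and the gene groups in the next paragraphs were chosen only after the result was seen.

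MHC class II genes, which present antigen to T cells, were higher in all 13 members tested in C4, with a median of 0.52 (adjusted p = 1.07e-11, and adjusted p = 0.0784 with an estimated correlation). In B3 5 were higher and 1 lower, with a median of 0.03 (adjusted p = 0.0857). Their activator CIITA was at 1.08 ± 0.04 and CD74, the invariant chain, at 0.39 ± 0.04 in C4, and these genes lie outside the shifted window on chromosome 6 that holds other members. HLA genes are alike in sequence, so their reads can be counted for each other. Cancer-testis genes of X-linked families, normally limited to germ cells, were lower in 15 of 22 and higher in 1 in B3 (median -0.30, adjusted p = 7.44e-10, and adjusted p = 0.00714 with an estimated correlation) and lower in 15 and higher in 4 in C4 (median -0.15, adjusted p = 0.000383, and adjusted p = 0.0506 with an estimated correlation). Of the 22, 12 were lower in both lines, 1 was higher in both and 3 went opposite ways, with MAGEC2 at 1.70 and MAGEC1 at 0.56 in C4. In C4 against B3 10 were higher and 4 lower (adjusted p = 0.0235, and adjusted p = 0.193 with an estimated correlation). Abundant members went different ways in B3: MAGEA3, MAGEA6, MAGEA11 and MAGEA12 were not called (0.02, -0.01, 0.01 and -0.03), MAGEA1 was at 0.27, and CTAG2 and MAGEA10 at -2.73 and -2.40. Some lower members had small wild-type values, such as MAGEA4 (4.14) and PAGE1 (4.66). The families were chosen with the falls of CTAG2, MAGEA10 and PAGE2 in view, so their p-values do not show a fall of whole families. Some copies in these families are near-identical, which leaves the counting of those members uncertain.

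ABCA5, ABCA6, ABCA8, ABCA9 and ABCA10, neighbouring lipid transporter genes on chromosome 17, were all 5 lower in both lines. The median was -0.43 in B3 (adjusted p = 1.26e-05, and adjusted p = 0.0337 with an estimated correlation) and -0.41 in C4 (adjusted p = 5.02e-05, and adjusted p = 0.0506 with an estimated correlation). ABCA8 and ABCA6, named above for their shared decreases, are part of the group, so these p-values in part restate their falls. The group was not tested without them. Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids onto tRNA, had 15 of 20 lower in C4, with a median of -0.31 (adjusted p = 4.21e-09, and adjusted p = 0.134 with an estimated correlation), and 3 higher and 6 lower in B3, with a median of -0.01. Examples in C4 were GARS (-0.81 ± 0.03), SARS (-0.80 ± 0.03) and CARS (-0.74 ± 0.02). Of the 17 mitochondrial synthetase genes 4 were higher and 6 lower in C4, with a median of -0.01 (adjusted p = 0.659).

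Neighbouring genes shifted together in runs in single lines, in 33 windows over both lines beyond the largest of 1000 shuffles, which argues against a random arrangement of the changed genes. A trend on GC content and transcript length is argued against by the 90.35% of the windows' median shift left after its removal. A few strong genes per window are argued against for 15 windows chosen on every other gene, where 91.12% of the 304 genes not used to choose them lay on the side of the shift, with a low of 12 of 20 in a window of C4 that is not among the 33, and the other windows of the 33 had no such check. Gains or losses of chromosome segments in a line may give such runs, but no DNA measurement was analysed here, so this is an untested hypothesis. The upward run, on chromosome 6 in C4, holds MHC class II genes of the group above and is not separate from their rise. CIITA and CD74, on other chromosomes, rose in C4 as well, at 1.08 and 0.39. Whether the runs arose before or after the knockout is open as well.

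The fold changes of the lines had a covariance 22.46 times the largest simulated with no effect, which argues against the spread between the shared WT libraries as the whole cause. Of the covariance over the 13451 genes in windows, 98% was left after subtracting the median of each gene's window in each line. That argues only against shared shifts of whole windows, and no window was shifted in both lines, so the subtraction could take little away. Shorter shared runs are not covered by it, and the neighbours ABCA5 to ABCA10 were all lower in both lines. The correlation across genes (0.375 against a simulated mean of 0.498) and the percent of genes with the same sign (63.0 against 66.6) lay below the values simulated with no effect. The simulated values come from the spread between libraries alone. They are no benchmark for lines with changes of their own, so these measures cannot tell whether the lines are alike beyond shared controls. Of 100 splits of the 9 libraries into 3 groups, 1, the real one, called as many genes the same way in both as the 3966 observed. Lines that differ for any cause would give this outcome, because other splits mix lines within a group. The splits thus show only that the libraries group by line, and they do not address differences between cultures or lines. The highest other splits gave 1727 and 1488, with the B3 libraries and the WT libraries in the place of the controls, and 97 of the other 99 gave 0, where mixing lines in a group also widens its spread. The loss of ARNT2 may account for shared changes, but so may the editing, growth from selected cells or a deviation common to all WT libraries, since the groups hold no line edited without a change in ARNT2 and no further controls.

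For B3 against wild type, 1 of 10 splits of the 6 libraries, the real one, gave as many as 7876 genes, and the highest other gave 0. For C4 against wild type it was likewise 1 of 10, with 9244 genes and 0. These splits are too few for a share under 0.05.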
